A study of Mus musculus with 6 samples.

How the data were processed

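Bulk RNA-seq was measured in CD4+CD8+ double positive thymocytes, the stage of T cell development at which the T cell receptor alpha locus is rearranged and receptors are tested for self recognition. Cells were sorted by flow cytometry from the thymus of male C57BL/6 mice as positive for CD45.2, CD4 and CD8 and negative for the B cell marker CD19, after red cells had been lysed, per the labels' protocols. The samples fall into 2 groups of 3 libraries, each library from an individual mouse. Control mice had an intact Suv39h1 on their X chromosome and were heterozygous for Suv39h2, so they were not wild type. Suv39DKO mice lacked both genes. Suv39h1 and Suv39h2 encode histone methyltransferases that place trimethylation on lysine 9 of histone H3, a mark of silent heterochromatin.

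PolyA RNA was extracted with the RNeasy Plus kit and made into TruSeq RNA libraries, per the labels' protocols. Base calls were converted with bcl2fastq and reads were counted per gene with featureCounts on mm10, per the submitters' processing notes. The aligner, the tool versions, the strand setting of the counting and the annotation release were not given in the sources used here. The deposited values are raw counts, whole numbers per gene, as the file headers and the values themselves show, with no normalization or filter. The 6 count columns of the deposited series table were the same as the single-library values, with 0 gene counts differing. Each library listed 55487 genes. Of these identifiers, 55094 matched GENCODE M21 with their version, all with the same exon length, and 93 were not found. Symbols, biotypes and mm10 coordinates were taken from that annotation, and 0 entries named no gene. Because the strand setting is not known, reads of a gene and of an overlapping antisense gene cannot be told apart in these counts.

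Total counts per library ran from 22670154 to 36849433, so 3 counts, the smallest number used as a detection floor, correspond to between 0.0821 and 0.134 counts per 1000000 (CPM) in a single library. Such floors, and the intervals given for shares of counts, cover counting error only, since reads without molecular identifiers are not independent molecules. Before averaging, the libraries of a group were compared by a chi-square test of their counts over genes. The chi-square per degree of freedom was between 7.47 and 11.3 for pairs of Control libraries and between 11.0 and 26.1 for pairs of Suv39DKO libraries, so no pair agreed within sampling noise.

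Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low genes were removed with the filterByExpr function by group, which left 15473 genes, and libraries were scaled by the trimmed mean of M values. The quasi-likelihood test with robust dispersion compared the groups with no further term, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. An adjusted p under 0.05 is called changed, higher or lower. Log2 fold changes are Suv39DKO minus Control, and their standard error (SE) was computed as the absolute log2 fold change divided by the square root of the F statistic. CPM values use the scaled library sizes and are given as mean ± SD with n = 3 mice per group. A gene with 0 counts in every library of a group is given a fold against a floor of 3 counts over that group, written as at least that many times lower. A gene with 1 to 3 counts in a group is given a count ratio with its exact 95% interval, from counts summed over each group. That interval covers counting error only and not the spread between mice.

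Gene lists and families, 39 in all, were fixed from textbook knowledge before the data were examined. They covered H3K9 methylation, Polycomb, germline genes, double positive identity, early thymocytes, positive selection, effector T cells, gamma delta and NK cells, B cells, myeloid cells, dendritic cells, erythroid cells, epithelium and stroma, interferon-stimulated genes, p53 targets, S phase, G2 and M phase, apoptosis, immediate early and heat shock stress, the unfolded protein response, DNA repair, cholesterol synthesis, oxidative phosphorylation, MHC class I, Notch, neuronal genes and Y-linked genes. Families by symbol were zinc finger proteins, protocadherins, olfactory and vomeronasal receptors, clustered multicopy families such as Speer and Xlr, histones, ribosomal proteins, mitochondrially encoded genes, killer cell lectin-like receptors, Schlafen and Gimap and related GTPases, predicted genes, serine protease inhibitors with kallikreins, and keratins. The 36 with 5 or more tested members were tested with camera from limma 3.58.1 at the preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. For each list the members past the threshold are counted over all tested genes and also adjusted over the list alone.

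The rule for named genes was also fixed before the data were examined. It took both targeted genes, the 12 largest rises and 12 largest falls among changed genes with a mean log2 CPM of at least 1, separated groups and a symbol that was not a predicted name, up to 6 genes of each detection class, and up to 4 changed members per list by adjusted p. Where no member of a list passed, up to 2 members of highest CPM were taken. Genes named outside this rule are said to be chosen after their values were seen.

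A gene was called detected at 0.5 CPM or more in every library of a group and silent under 0.5 CPM in every library. Changed genes near the targeted loci, within 10 Mb, and near centromeres, in the first 15 Mb of an autosome, were compared with other tested genes by Fisher's exact test, two-sided. Adjacent pairs of genes changed in the same direction were set against 10000 random placements of the calls. The distance between libraries was Euclidean over log2 CPM with a prior count of 2. Measures per library were compared with a two-sided exact permutation test, in which 3 mice against 3 cannot give a p below 0.1. Intervals of list medians came from 10000 bootstrap draws of the members, and correlations across gene segments were tested with 100000 permutations.

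The steps were tested on simulated data with 200 changed genes among 15473. For Suv39DKO against Control, edgeR recovered 62% of genes changed 1.5-fold, 78% of those changed 2-fold, 100% of those raised 4-fold and 94% of those lowered 4-fold, with 17 false calls. Planted detection switches were all found, 30 of 30 in each direction, and simulated libraries with none planted gave 16 gains and 25 losses. The planted list was called by camera and 0 of 20 random lists were. Genes were drawn independently in this simulation, so it holds no inter-gene correlation and gives no false call rate for camera on these lists.

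Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, upper-quartile scaling, library size alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 and limma-voom as tests, the replicate number as a block, non-robust dispersion, a minimum fold of 1.5, removal of the 20 most abundant genes, the series table, each library left out in turn, other detection levels, other windows, other list tests, neighbouring pairs without members of the same family, and distances over the 500 most variable genes. The count of neighbouring pairs without chromosome 12 was added after seeing the data. Tables were handled in Python 3.11.15 with pandas 2.3.3 and figures drawn with matplotlib 3.10.9. No sample was left out.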

Results

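Gene expression was compared between double positive thymocytes of 3 Control and 3 Suv39DKO male mice, to ask how these cells differ when both Suv39h methyltransferases are missing. Control libraries held 36849433, 26957797 and 31260328 counts for replicates 1, 2 and 3, and Suv39DKO libraries held 30774990, 22670154 and 25048118. Replicate numbers only number the mice. After thinning to the smallest total, 21688 ± 232 genes had a count in Control and 20979 ± 662 in Suv39DKO (SD, n = 3; exact permutation p = 0.1, the smallest p that 3 mice against 3 allow). Every Control library lay above every Suv39DKO library in that number. Mitochondrially encoded genes took 2.21 ± 0.05% of counts in Control and 2.02 ± 0.48% in Suv39DKO (SD, n = 3; exact permutation p = 0.7), with 1.49% in Suv39DKO replicate 1.

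Both targeted genes were lower in every Suv39DKO library. Suv39h1 (ENSMUSG00000039231.18, mm10 chromosome X, 8061171 to 8074760) fell from 77.4 ± 6.44 CPM to 0.304 ± 0.270 CPM, with 2016 to 3096 counts per Control library and 1 to 13 counts per Suv39DKO library. Its log2 fold change was -8.02 (SE 0.29, edgeR adjusted p = 4.83e-07). Suv39h2 (ENSMUSG00000026646.16, chromosome 2, 3455815 to 3475031) fell from 7.25 ± 1.84 CPM in the heterozygous controls to 2.27 ± 0.38 CPM, a log2 fold change of -1.67 (SE 0.23, edgeR adjusted p = 3.92e-04). Suv39h2 kept 41 to 78 counts in the Suv39DKO libraries. The deleted part of each gene is not given in the sources used here, so gene-level counts cannot tell reads outside a deletion from an intact transcript.

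Loss of both enzymes went with 2215 changed genes of 15473 tested (14.3%), of which 997 were higher and 1218 lower in Suv39DKO. Falls were the larger changes. The median log2 fold change was 0.43 among higher genes and -0.94 among lower genes, and 575 genes fell at least 2-fold against 160 that rose as much. Protein-coding genes made up 861 of the higher and 1053 of the lower genes, and predicted, clone-named or accession-named genes 113 and 157. Over all tested genes, the 3 libraries of one genotype lay outside the range of the other in 5154, or 33.3%, against 10% by chance with 3 mice against 3. With a minimum fold of 1.5 in the test, 510 genes were called, 110 higher and 400 lower. Leaving out Control replicate 1, 2 or 3 left 1305, 1209 or 1305 changed genes, and leaving out Suv39DKO replicate 1, 2 or 3 left 2224, 2001 or 2085.

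The largest rises at a mean log2 CPM of at least 1, predicted names left out, included a kinase gene, receptors, a transcription factor and J segments of the T cell receptor alpha locus. Larger rises, of at least 16-fold, were found in 21 genes, 20 of them on chromosome 12. Gfra1, a co-receptor for the neurotrophic factor GDNF, rose from 12.5 ± 2.16 to 78.8 ± 20.3 CPM (log2 fold change 2.65, SE 0.21, edgeR adjusted p = 1.53e-04). Olig3, a transcription factor of the developing nervous system, rose from 7.26 ± 2.16 to 45.4 ± 5.65 CPM (2.64, SE 0.19, edgeR adjusted p = 1.31e-05). Kit, the stem cell factor receptor carried by the earliest thymocytes, rose from 2.83 ± 0.43 to 16.8 ± 6.08 CPM (2.56, SE 0.25, edgeR adjusted p = 6.81e-05). Log2 rises among the other named genes were 2.92 for Cdc42bpa, 2.80 for Fjx1, 2.38 for Elfn2, 2.09 for B3galt5 and 1.99 for Ly6k. The segments Traj61, Traj58, Traj59 and Traj60 rose by 2.39, 2.13, 2.00 and 1.96. The call of Cdc42bpa was lost without Control replicate 1 (edgeR adjusted p = 0.0701). Ly6k was lost without any 1 Control replicate or without Suv39DKO replicate 2 (edgeR adjusted p from 0.102 to 0.135) and without the low-count filter (0.10).

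Among genes at a mean log2 CPM of at least 1, several genes fell to near or below detection. Tox3, a nuclear protein of the HMG box family, had 6.38 ± 1.94 CPM in Control and 0 counts in Suv39DKO, at least 167-fold lower against a floor of 3 counts over the group. Slit3, a secreted guidance ligand, went from 4.96 ± 1.29 CPM to 0 counts, at least 126-fold lower. Prdm16, a zinc finger protein with reported H3K9 methyltransferase activity, went from 4.03 ± 0.61 CPM to 0 counts, at least 103-fold lower. Slc7a11, the cystine transporter, fell from 178 ± 33.1 to 1.10 ± 0.53 CPM (log2 fold change -7.36, SE 0.28, edgeR adjusted p = 1.16e-05). Pcsk1, a prohormone-processing protease, fell from 28.2 ± 0.82 to 0.108 ± 0.150 CPM (-8.04, SE 0.38, edgeR adjusted p = 4.83e-07). Ddx3y, a Y-linked RNA helicase, fell from 111 ± 10.5 to 0.399 ± 0.436 CPM (-8.25, SE 0.41, edgeR adjusted p = 9.40e-05). Eps8l1 (-7.65), Acpp (-6.74), Hoxa7 (-5.84), the DNA sensor Aim2 (-5.74) and Pax7 (-5.55) were the other falls taken at that level; genes of lower level, such as Hoxa5, Xlr3b and Prss50, went to 0 counts. The call of Eps8l1, which varied widely among controls (SD 12.7 CPM), was lost without Suv39DKO replicate 1 or 3 (edgeR adjusted p = 0.0740 and 0.0563).

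**Figure D1:**
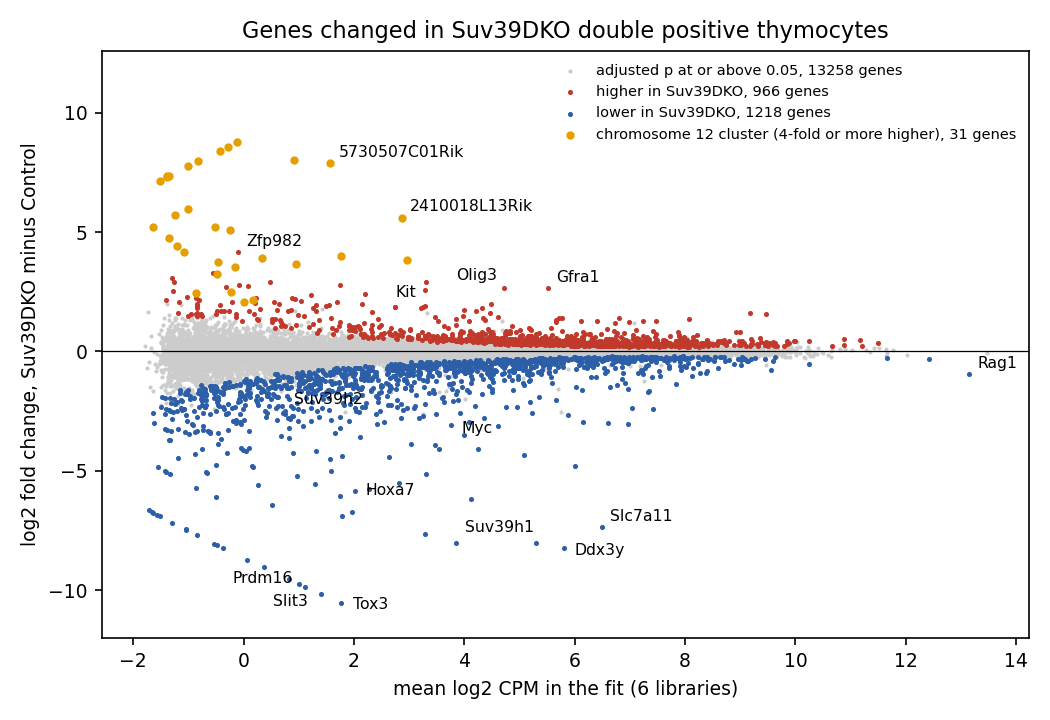
Each point is 1 of 15473 tested genes, with the mean log2 CPM of the 6 libraries on the x axis and the fitted log2 fold change, Suv39DKO minus Control, on the y axis. Grey points did not pass, red points were higher, blue points were lower, and orange points are the 31 genes of the chromosome 12 cluster that rose at least 4-fold; fitted folds of genes with 0 counts in a group, such as Tox3, Slit3 and Prdm16, depend on a prior count.

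Genes that switched between silent and detected were mostly losses. Changed genes among them were counted in a separate edgeR fit without the low-count filter. From silent to detected there were 64 genes, 46 of them changed in that fit, and 25 of the 64, all changed, lay on chromosome 12. From detected to silent there were 198 genes, 155 of them changed in that fit, and those were spread over 20 chromosomes. Levels were low in both classes. The median was 0.893 CPM in Control for losses and 0.836 CPM in Suv39DKO for gains, with 12 losses and 2 gains at 5 CPM or more. Silent means under 0.5 CPM and not 0 counts, so a switch can be a small shift across that level. Named gains were Sall3 (0.254 ± 0.187 to 1.77 ± 0.61 CPM, log2 fold change 2.76), Zfp982 (4.16), Myo1e (2.78), the pseudogene Rps19-ps1 (2.08), the inhibitory Fc receptor Fcgr2b (2.71) and Hebp2 (3.30). Named losses were Pcsk1, Eps8l1, Aim2, Hoxa7, Acpp and the amino acid transporter Slc36a4, which fell from 13.3 ± 1.37 to 0.293 ± 0.175 CPM (log2 fold change -5.53, SE 0.27). Rps19-ps1 lies among the V segments of the T cell receptor alpha locus, and its call was lost in 4 of the 6 fits without a library (edgeR adjusted p from 0.0539 to 0.163). Leaving out Suv39DKO replicate 1 or 2 gave 101 or 99 gains, in part because fewer libraries had to pass.

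The 31 genes of chromosome 12 that rose at least 4-fold lay between 17900734 and 24252181, a span chosen after its values were seen. They made up 31 of the 61 genes of the genome that rose this much, and 29 of them were not protein-coding. Some of the 31 overlap each other in position, so they need not be separate transcripts. Over the whole span 34 of 49 tested genes were higher and 1 was lower. The summed level of the 31 genes was 3.95 CPM in Control and 78.6 CPM in Suv39DKO. The noncoding gene 2410018L13Rik rose from 0.292 ± 0.028 to 14.5 ± 1.42 CPM (log2 fold change 5.61, SE 0.21, edgeR adjusted p = 8.51e-09). The coding genes 5730507C01Rik and 9030624G23Rik had 2 counts and 1 count in all controls together. They were higher by count ratios of 289 (95% interval of counting error only, 79.7 to 2396) and 362 (64.5 to 14341). A median share of 0.14 of a member's 75-base words was also found in another gene, with 0.582 the highest.

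**Figure D2:**
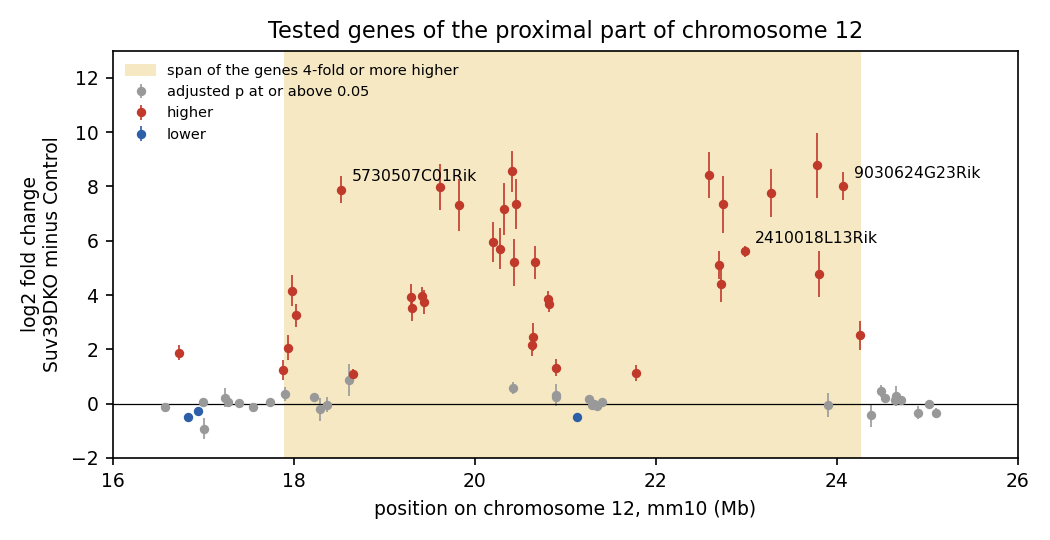
Tested genes of the proximal part of chromosome 12 are placed by position (mm10, Mb) on the x axis, with the log2 fold change, Suv39DKO minus Control, on the y axis and bars of 1 SE. Red genes were higher, blue genes lower and grey genes did not pass; the shaded span from 17900734 to 24252181 holds the 31 genes that rose at least 4-fold.

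Changed genes lay next to each other along chromosomes more often than placed by chance. There were 135 adjacent pairs of higher genes against a mean of 64.1 in random placements, and 196 pairs of lower genes against 95.7 (permutation p = 1e-04 for each, the smallest that 10000 placements can give). An example chosen after its values were seen is the Hoxa cluster of chromosome 6. Hoxa3, Hoxa4, Hoxa5, Hoxa6 and Hoxa7 all fell there, Hoxa5 from 3.17 ± 0.59 CPM to 0 counts. Hoxa3 as annotated spans Hoxa4, Hoxa5 and Hoxa6. Overlapping genes were kept in the counts of pairs, so some pairs may come from a shared transcript. Within 10 Mb of Suv39h1 or Suv39h2, 11 of 102 tested genes were changed (10.8%) against 14.3% elsewhere (odds ratio 0.72, Fisher's exact p = 0.394). In the first 15 Mb of autosomes, next to the centromere, 4.61% of genes were higher against 6.70% elsewhere (odds ratio 0.67, Fisher's exact p = 0.00340), and 7.32% were lower against 7.90% (odds ratio 0.92, Fisher's exact p = 0.511). The difference for higher genes was lost with the first 10 Mb (odds ratio 0.73, Fisher's exact p = 0.0535) or 30 Mb (0.94, p = 0.447). With 5 Mb around the targeted genes the odds ratio was 0.36 (Fisher's exact p = 0.0389).

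Some double positive identity genes rose and others fell. Of 41 tested members, 10 were higher and 9 lower (adjusted over the list alone, 16 and 11), and the list was not called (camera adjusted p = 0.619). The recombinase genes fell, Rag1 from 11969 ± 400 to 6214 ± 413 CPM (log2 fold change -0.95, SE 0.07, edgeR adjusted p = 3.43e-06) and Rag2 by a log2 change of -0.68, as did the costimulatory receptor Cd28 (-0.83) and Slc7a11. Cd4 (0.47), Dntt (0.35) and Rorc (0.30) rose, while Cd8a (0.09) and Cd3e (0.05) did not pass; these were chosen after their values were seen. Of 22 early thymocyte genes 8 were higher and 5 lower (list alone 9 and 6; camera adjusted p = 0.601). Kit and Cd93 (1.80) rose, and Myc, which drives growth, fell from 23.6 ± 5.91 to 2.84 ± 0.39 CPM (-3.06), as did Cd44 (-1.62) and, outside the naming rule, Il7r (-2.30), Cdkn1c (-1.20) and Tcf7 (-0.33). In the Notch pathway 3 of 20 members were higher, Dtx1 (1.33), Notch3 (0.59) and Hes6 (0.43), and 3 were lower, Myc and, outside the naming rule, Lfng (-1.63) and Jag2 (-0.75). Adjusted over the list alone these were 4 and 6 (camera adjusted p = 0.647). Without Control replicate 1, 2 or 3 there were 6, 6 or 5 higher identity genes and 5 higher early thymocyte genes each time.

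The list of genes induced at positive selection and in mature single positive T cells was called lower by camera, with members in both directions. Of 47 tested members 20 were lower, 5 were higher and 22 did not pass (adjusted over the list alone, 24 and 6; camera adjusted p = 4.89e-05; adjusted p = 0.764 with an estimated correlation). The tetraspanin Cd53 fell from 25.7 ± 1.41 to 4.20 ± 1.11 CPM (log2 fold change -2.60), Runx3, a regulator of the CD8 lineage, from 18.9 ± 2.17 to 4.90 ± 0.69 CPM (-1.95), and the chemokine receptor Ccr7 from 8.53 ± 1.32 to 1.94 ± 0.68 CPM (-2.13). Socs3, an inhibitor of cytokine signalling, rose from 49.6 ± 3.47 to 119 ± 22.6 CPM (1.26), as did, outside the naming rule, Pdlim4 (1.69), Tox2 (1.03), Bcl2 (0.45) and Gimap6 (0.44). The per-library median of the list was -0.36, -0.37 and -0.50 in the 3 Suv39DKO libraries. Lower members numbered 13 without Control replicate 1, and higher members 3 without Control replicate 2 or 3. Of 18 effector genes 2 were higher, Gzma (1.22) and Il12rb1 (0.36), and 2 lower, Prf1 (-1.57) and Prdm1 (-1.31), the same numbers over the list alone (camera adjusted p = 0.766). Leaving out 1 replicate ended the calls of Il12rb1 (Control 1 or 2, edgeR adjusted p up to 0.0664) and Prdm1 (Control 1 or 3 or Suv39DKO 2, up to 0.157).

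The list of gamma delta, NK and innate-like genes was called higher by camera on a minority of its members. Of 14 tested members 4 were higher, 0 were lower and 10 did not pass (adjusted over the list alone, 4 and 0; camera adjusted p = 0.00453; adjusted p = 0.397 with an estimated correlation). Trdc, the constant segment of the T cell receptor delta chain, rose from 75.6 ± 2.48 to 179 ± 24.9 CPM (log2 fold change 1.24, SE 0.09, edgeR adjusted p = 3.47e-06). Granzyme A (Gzma) rose from 30.6 ± 5.32 to 71.1 ± 5.49 CPM (1.22), the gamma constant segment Tcrg-C1 from 1.12 ± 0.45 to 3.11 ± 0.13 CPM (1.49), and the transcription factor Maf by 1.74. Trdc lies inside the T cell receptor alpha locus and is deleted by rearrangement of that locus. The killer cell lectin-like receptor family had a single tested member, Klrb1f, at 0.588 ± 0.073 and 0.766 ± 0.480 CPM, which did not pass (0 higher, 0 lower, also over the list alone).

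The change in J segment counts at the T cell receptor alpha locus differed with position. Of 39 tested J segments, 4 were higher, all of them at the end nearest the V segments, and 9 were lower, all in the part nearest the constant segment. Traj61 rose from 1.49 ± 0.27 to 7.76 ± 1.11 CPM, while Traj1 fell from 3.34 to 1.28 CPM (log2 fold change -1.38, SE 0.24). The J segments of the V-proximal part took 30.1 ± 1.05% of all J segment counts in Control and 65.1 ± 6.56% in Suv39DKO (SD, n = 3; exact permutation p = 0.1, the smallest possible), higher in 3 of 3 mice. That share rests on the 4 outermost segments: the median log2 fold change was -0.37 over the V-proximal part and -1.15 over the other part, and Traj28 (-1.16) and Traj27 (-1.37), in the V-proximal part, did not pass. Each library had 1102 to 1630 J segment counts. The constant segment Trac had 611 ± 13.1 and 545 ± 31.8 CPM and did not pass (log2 fold change -0.17, SE 0.06, edgeR adjusted p = 0.113). Apart from the segments Traj61, Traj58, Traj59 and Traj60, which the naming rule took, this locus was chosen after its values were seen.

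**Figure D3:**
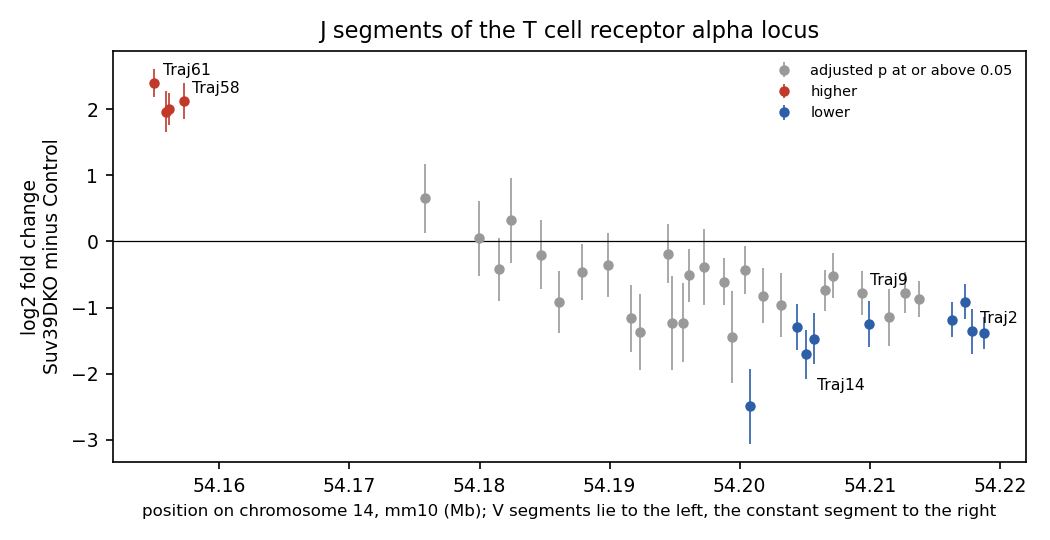
The 39 tested J segments of the T cell receptor alpha locus are placed by position on chromosome 14 (mm10, Mb) on the x axis, with the log2 fold change, Suv39DKO minus Control, on the y axis and bars of 1 SE. The 4 red segments nearest the V segments were higher, from 1.96 to 2.39, and the 9 blue segments towards the constant segment were lower.

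The list of mitotic genes was called higher by camera, with library medians above Control in Suv39DKO replicates 2 and 3 and near it in replicate 1. Of 52 tested G2 and M phase genes 17 were higher and 0 lower (adjusted over the list alone, 24 and 0; camera adjusted p = 1.06e-06; adjusted p = 0.860 with an estimated correlation). Examples are Tubb4b (log2 fold change 0.49), the centromeric histone Cenpa (0.47), Tacc3 (0.45) and the kinetochore gene Ndc80 (0.44). The list median relative to Control was 0.01, 0.39 and 0.40 in Suv39DKO replicates 1, 2 and 3. Without Suv39DKO replicate 1, 2 or 3 there were 43, 7 or 6 higher members, without Control replicate 1, 2 or 3 there were 5, 5 or 3, and with the replicate number as a block there were 9. Of 49 S phase genes 3 were higher, Cdca7 (0.51), Blm (0.39) and Chaf1b (0.28), and 0 lower (list alone 1 and 0; camera adjusted p = 0.347). Leaving out 1 replicate ended the calls of Ndc80 (Control 1 or 3, edgeR adjusted p up to 0.0590), Blm (Control 1 or 2 or Suv39DKO 1 or 3, up to 0.165) and Chaf1b (any but Suv39DKO 3, up to 0.170).

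The histone list was called higher by camera, with a median log2 fold change of 0.70, while the replication-independent linker histone fell. Of 38 tested histone genes 4 were higher, 1 was lower and 33 did not pass (adjusted over the list alone, 4 and 1; camera adjusted p = 0.00464; adjusted p = 0.559 with an estimated correlation). Hist1h1e rose from 0.404 ± 0.118 to 1.92 ± 0.33 CPM (2.24), Hist1h2ab by 1.71 and Hist1h3i by 1.59, as did Hist1h3e, chosen after its value was seen. H1f0, expressed independently of replication, fell from 63.7 ± 7.31 to 10.5 ± 4.19 CPM (-2.59). The family as counted, H1f0 included, took 0.0194 ± 0.0025% of counts in Control and 0.0172 ± 0.0022% in Suv39DKO (SD, n = 3, exact permutation p = 0.3). The fall of H1f0 enters these shares, so they do not give the direction of the replication-dependent histones. Transcripts of replication-dependent histones mostly lack polyA tails and come from near-identical copies, so their low polyA counts are uncertain. Histone medians per Suv39DKO library were 0.36, 0.63 and 0.66, again lowest in replicate 1. Without any 1 Control replicate or Suv39DKO replicate 3, 2 members were higher, and Hist1h3i lost its call (edgeR adjusted p up to 0.108).

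Oxidative phosphorylation genes were called higher with few single genes passing. Of 49 members 2 were higher, Atp5h (0.46) and Ndufa8 (0.29), and 0 lower (adjusted over the list alone, 1 and 0; camera adjusted p = 0.0116; adjusted p = 0.860 with an estimated correlation). The library medians were 0.32, 0.15 and -0.03 in Suv39DKO replicates 1, 2 and 3, and the list call was lost without Control replicate 3 (adjusted p = 0.0530) or Suv39DKO replicate 1 (adjusted p = 0.201), while 4 or 13 members were higher without Suv39DKO replicate 2 or 3 and 1 without any other. Of 80 ribosomal protein genes 0 were higher and 0 lower, the same over the list alone (camera adjusted p = 0.438), with Rps3 at 996 ± 16.3 and 1046 ± 235 CPM and Rpl8 at 985 ± 30.5 and 959 ± 74.7 CPM. Without Suv39DKO replicate 1 the ribosomal list was called lower (camera adjusted p = 0.00180), and without Suv39DKO replicate 2 there were 3 lower ribosomal and 5 lower mitochondrial members. Of 19 mitochondrially encoded genes 1 was lower, the transfer RNA mt-Tp (-0.53), and 0 over the list alone (camera adjusted p = 0.293), a list called only without Suv39DKO replicate 2 (adjusted p = 3.21e-04). Leaving out 1 replicate ended the calls of Ndufa8 (any Control or Suv39DKO 1, edgeR adjusted p up to 0.124) and mt-Tp (Control 1 or 2 or Suv39DKO 1 or 3, up to 0.140).

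**Figure D4:**
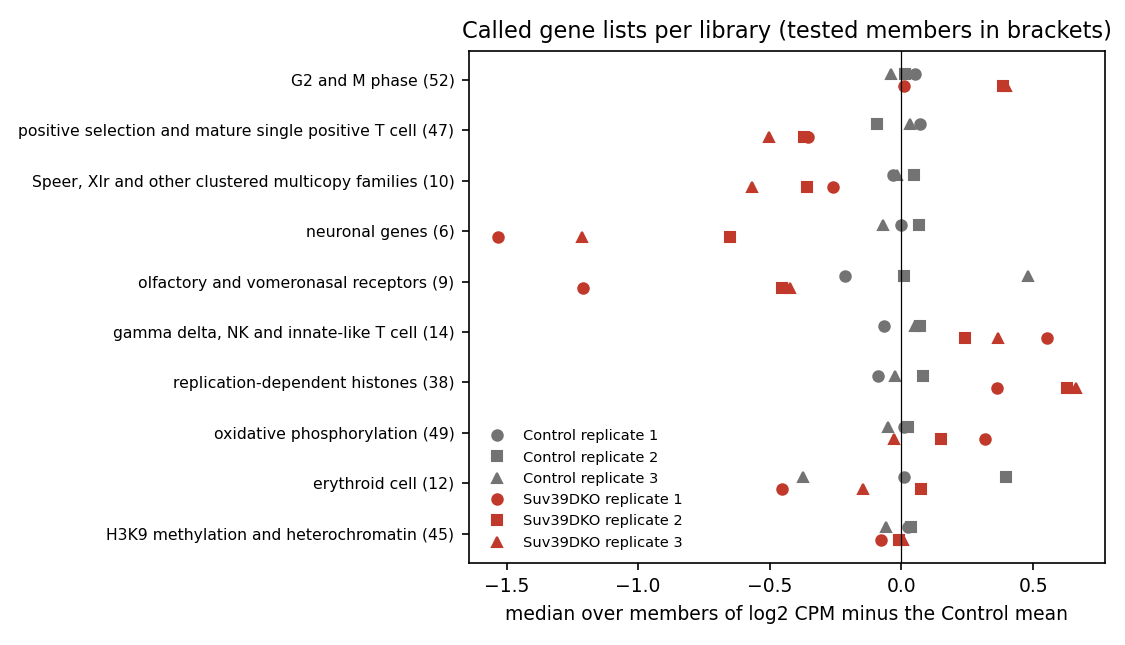
For each of the 10 called lists, each symbol is the median over its tested members of log2 CPM minus the Control mean in 1 library (x axis, log2 units); grey symbols are Control and red symbols Suv39DKO mice. Suv39DKO replicate 1 lies with the controls for G2 and M phase genes, at 0.01, where replicates 2 and 3 lie at 0.39 and 0.40.

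Some chromatin regulators beyond the targeted genes passed the test, as did 14.3% of all tested genes. Of 45 tested H3K9 methylation and heterochromatin genes 5 were lower and 2 higher, the same over the list alone (adjusted over the list alone, 5 and 2; camera adjusted p = 0.0168; adjusted p = 0.860 with an estimated correlation). The lower members were Suv39h1, Suv39h2 and Prdm16, the adaptor Atf7ip (258 ± 12.1 to 159 ± 13.3 CPM, log2 fold change -0.70) and, outside the naming rule, Pphln1 (-0.24). The higher members, also outside it, were Setdb2 (0.36) and Kdm3a (0.27). The list median was -0.00, and its call was lost without Control replicate 2 (adjusted p = 0.0628) or Suv39DKO replicate 1 (adjusted p = 0.0607). The list holds both targeted genes, whose fall the genotype sets, and camera was not run without them. Its call therefore says nothing of the other members as a set. Of 31 Polycomb genes 4 were lower, Epop (-2.50), Cbx7 (-0.42), Cbx6 (-0.26) and Suz12 (-0.23), and 1 higher, Cbx4 (0.28), chosen after its value was seen (list alone 5 and 2; camera adjusted p = 0.603). Calls ended when 1 replicate was left out for Cbx7 (Control 3, edgeR adjusted p = 0.0691), Cbx6 (Control 1 or 2 or Suv39DKO 3, up to 0.113) and Suz12 (any but Suv39DKO 2, up to 0.183). The H3K9 list had 0 higher members without any 1 library other than Suv39DKO replicate 2, and 2 Polycomb genes were lower without any 1 Control replicate or Suv39DKO replicate 3.

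The lists of clustered multicopy families, of olfactory and vomeronasal receptors and of neuronal genes were called lower by camera. Most annotated members did not pass the low-count filter, which left 10 of 219, 9 of 1972 and 6 of 40 genes in that order. These calls therefore cover only the few tested members. Of 10 tested genes of clustered multicopy families 5 were lower and 0 higher (adjusted over the list alone, 5 and 0; camera adjusted p = 0.00226; adjusted p = 0.397 with an estimated correlation). Xlr3b went from 1.18 ± 0.68 CPM to 0 counts, at least 29.5-fold lower, and Pramef8 fell by 0.94, Xlr4e-ps by 1.91 and the nuclear body gene Sp100 by 0.43 on the log2 scale. The member Slx4ip (-0.47), named after its value was seen, matched the symbol pattern without belonging to such a family. Of 9 olfactory and vomeronasal receptors 4 were lower and 0 higher, the same over the list alone (adjusted over the list alone, 4 and 0; camera adjusted p = 0.00453; adjusted p = 0.575 with an estimated correlation). They were Vmn2r97 (15.5 ± 6.25 to 2.19 ± 0.88 CPM), Vmn2r84 (-0.63), Olfr1033 and Vmn2r96, the last pair at under 1 CPM with count ratios of 68.9 (95% interval 12 to 2755) and 21.9 (7.22 to 108) between Control and Suv39DKO. The list call was lost without Suv39DKO replicate 1 (adjusted p = 0.0607), and that of Vmn2r84 without any 1 Control replicate (edgeR adjusted p up to 0.143). Neuronal genes had 2 of 6 members lower, Ncam1 (-4.78) and the glutamate receptor Gria2 (-1.16), and 0 higher (adjusted over the list alone, 4 and 0; camera adjusted p = 0.00453; adjusted p = 0.397 with an estimated correlation), with 4 lower without Suv39DKO replicate 2. Reads of these families can be shared between paralogs.

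Germline genes, which H3K9 methylation can silence, were not called as a list. Of 82 annotated members 19 passed the low-count filter, and the others were not tested. Of 19 tested members 3 were higher, Tdrd5 (0.68) and, outside the naming rule, Brdt (0.71) and Spo11 (0.37), and 3 lower, Prss50 (0.781 ± 0.240 CPM to 0 counts, at least 20-fold lower), Xlr3b and Mei4 (-1.16). The numbers were the same over the list alone (camera adjusted p = 0.603). Of 343 zinc finger genes 11 were higher and 29 lower (list alone 9 and 28; camera adjusted p = 0.511), with Zfp982 higher and Zfp580 (-2.31) and Zfp831 (-2.14) lower. Without Control replicate 1, 2 or 3 there were 3, 3 or 4 higher zinc finger genes and 19, 23 or 16 lower. Zfp951 fell from 2.57 ± 0.30 to 0.0257 ± 0.0231 CPM, a count ratio of 99.3 (95% interval 27.2 to 825). Of 9 protocadherins 2 were higher, Pcdhgc3 and Pcdhgc4 (1.03 each), and 1 lower, Pcdhga12 (-1.54), in genes that share 3 prime exons (list alone 3 and 1; camera adjusted p = 0.347). Of 3554 predicted genes, accession-like names not included, 104 were higher and 142 lower (list alone 70 and 89; camera adjusted p = 0.913), the 4 with the smallest adjusted p being 2410018L13Rik, 5730507C01Rik, 9030624G23Rik and 4921525O09Rik (-2.11). Without Control replicate 1, 2 or 3 there were 71, 60 or 71 higher predicted genes and 86, 80 or 74 lower. Of 5 serine protease inhibitors and kallikreins 2 were higher, Serpinb6a (0.50) and Serpinb9 (0.52), and Klk8 (-2.79) was lower, and of 4 keratins Krt10 (-1.51) was lower and 0 higher, with the same numbers over each list alone (camera adjusted p = 0.964 for the former, the latter too short to test). Calls ended when 1 replicate was left out for Pcdhgc4 (Control 2 or 3 or Suv39DKO 3, edgeR adjusted p up to 0.0849), Pcdhga12 (any but Suv39DKO 1, up to 0.115), Serpinb6a (Control 1 or 2 or Suv39DKO 1, up to 0.127) and Serpinb9 (any Control or Suv39DKO 3, up to 0.151).

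A few interferon-stimulated genes changed strongly, some up and others down, and the list was not called. Of 61 tested members 14 were higher, 9 were lower and 38 did not pass (adjusted over the list alone, 16 and 10; camera adjusted p = 0.741). Epsti1 fell from 124 ± 6.69 to 4.46 ± 0.55 CPM (log2 fold change -4.80, SE 0.11), Ifi209 from 35.5 ± 4.42 to 2.09 ± 0.66 CPM (-4.08) and Ifi208 by 2.54 on the log2 scale. Usp18 rose from 4.13 ± 0.48 to 15.1 ± 2.79 CPM (1.88). Of 28 Schlafen, Gimap and related GTPase genes 5 were higher, Gimap6 (0.44) and, outside the naming rule, Gbp7 (0.56), Gimap1os (0.48), Slfn5 (0.42) and Gbp2 (0.33), and 6 lower, with Gbp6 at -2.64, Gbp4 at -0.89 and Gbp8, which overlaps Gbp4, at -1.32 (list alone 8 and 7; camera adjusted p = 0.587). Of 24 MHC class I genes 3 were higher, Psmb10 (0.37) and, outside the naming rule, H2-T23 (0.37) and Tap1 (0.20), and 3 lower, H2-K1 (-0.60), Erap1 (-0.37) and H2-D1 (-0.26), with 8 and 4 over the list alone (camera adjusted p = 0.659). Without Control replicate 1, 2 or 3 there were 8, 8 or 9 higher interferon-stimulated genes, 2, 2 or 3 higher GTPase genes and 1 higher MHC class I gene each time, and without Suv39DKO replicate 3 there were 6 of the last. H2-D1 lost its call without any 1 Control replicate or Suv39DKO replicate 3 (edgeR adjusted p up to 0.0636).

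Some survival and stress genes rose and others fell, and none of these lists was called. Of 29 apoptosis regulators 8 were higher, with Casp3 at 0.45 and the survival gene Bcl2l1 at 0.38, and 4 lower, with the death-promoting Bmf falling from 247 to 77.9 CPM (-1.67), Bid at -0.46 and, chosen after their values were seen, Tnfrsf10b (-0.87) and Bik (-1.40) (list alone 8 and 4; camera adjusted p = 0.603). Of 43 p53 targets 5 were higher, with Tnfaip8 at 0.42, Ckap2 at 0.64, Def6 at 0.27, Fas at 0.43 and, outside the naming rule, Btg2 at 0.43, and 2 lower (list alone 5 and 3; camera adjusted p = 0.550); the lower ones, named after their values were seen, were Dglucy (-1.04) and Tnfrsf10b. Of 32 unfolded protein and integrated stress response genes 5 were higher, Phgdh (0.45) and, chosen after their values were seen, Sdf2l1 (0.43), Atf4 (0.33), Edem1 (0.28) and Hspa5 (0.27), and 3 lower (list alone 7 and 4; camera adjusted p = 0.659), namely Slc7a11, its partner subunit Slc3a2 (106 ± 6.18 to 50.5 ± 0.73 CPM, -1.08) and Xbp1 (-0.59). Of 31 immediate early and heat shock genes 4 were higher, Socs3, Dnajb1 (0.61), Klf6 (0.30) and Btg2, and 4 lower, Ier2 (-0.50) and, outside the naming rule, Nr4a1 (-0.40), Zfp36 (-0.33) and Fosb (-1.37) (list alone 5 and 5; camera adjusted p = 0.521). Of 39 DNA repair genes 2 were higher, Lig4 (0.47) and Blm, and 5 lower, with Atm at -0.33, Fanci at -0.42, Xrcc5 at -0.46 and, outside the naming rule, Chek2 at -0.46 and Prkdc at -0.34, the same over the list alone (camera adjusted p = 0.587). Of 25 cholesterol synthesis genes 1 was lower, Pcsk9 (-1.88), and 0 higher, the same over the list alone (camera adjusted p = 0.955).

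Several of these calls were lost with 1 library left out, in fits that have fewer mice; the log2 fold change of Fas was 0.43 with all mice and 0.41 to 0.44 in the fits that lost its call. Without Control replicate 1, 2 or 3 there were 6, 3 or 3 higher apoptosis regulators and 2 lower each time. Unfolded protein response genes had 2, 1 or 1 higher members in those fits and 3 without any 1 Suv39DKO replicate. For p53 targets 1 or 3 were higher and 0 lower without Control replicate 2 or 3, and lower immediate early genes numbered 0 without Control replicate 1 and 2 or 3 in the other such fits. Lower DNA repair genes numbered 3, 0 or 1 without Control replicate 1, 2 or 3 and 4, 1 or 2 without Suv39DKO replicate 1, 2 or 3. Leaving out 1 replicate ended the calls of the p53 targets Ckap2 (Control 2, edgeR adjusted p = 0.0524), Def6 (Control 2, 0.0640) and Fas (any Control, up to 0.0714). It also ended those of Phgdh (Control 1, edgeR adjusted p = 0.0518), Dnajb1 (Control 2 or Suv39DKO 1, up to 0.0748), Klf6 (Control 2 or 3 or Suv39DKO 3, up to 0.0885) and Ier2 (Control 1 or 3 or Suv39DKO 2, up to 0.104). Among DNA repair genes it ended those of Fanci (Control 2 or 3 or Suv39DKO 2, edgeR adjusted p up to 0.0851), Atm (Control 1 or 2 or Suv39DKO 2, up to 0.10) and Xrcc5 (Control 2 or 3 or Suv39DKO 3, up to 0.112).

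Among the lists for B, myeloid, dendritic, erythroid and stromal cells, which a thymus sort could hold, camera called the erythroid list alone. Of 12 erythroid genes 2 were lower and 0 higher, the same over the list alone (adjusted over the list alone, 2 and 0; camera adjusted p = 0.0158; adjusted p = 0.860 with an estimated correlation). These were Car2, a carbonic anhydrase that other cells also make (21.5 ± 1.82 to 1.23 ± 0.28 CPM, -4.10), and the mitochondrial iron importer Slc25a37 (-0.36), while haemoglobin genes took 0.0131 ± 0.0055% and 0.0121 ± 0.0015% of counts (SD, n = 3; exact permutation p = 0.9). The erythroid call was lost without Control replicate 2 (adjusted p = 0.262), Suv39DKO replicate 1 (0.0607) or Suv39DKO replicate 3 (0.0770). Of 15 B cell genes 2 were lower, Ly6d (-1.03), which thymocytes also express, and Vpreb3 (-2.64), and 0 higher (list alone 2 and 0; camera adjusted p = 0.451). Of 27 myeloid genes 1 was higher, Fcgr2b, and 4 lower, Axl (-0.86), Apoe (-0.52), Ccr2 (-2.92) and, outside the naming rule, Mafb (-0.58), the same over the list alone (camera adjusted p = 0.496). Of 17 dendritic cell and MHC class II genes 1 was higher, Tcf4 (0.30), and 2 lower, Ly6d and Irf4 (-0.67), with 3 and 3 over the list alone (camera adjusted p = 0.347). Of 10 epithelial and stromal genes 1 was higher, Pdgfrb (1.01), and 2 lower, Ctsl (-0.69) and Epcam (-1.43), with 1 and 3 over the list alone (camera adjusted p = 0.329). Leaving out 1 replicate ended the calls of Vpreb3 (Control 2 or 3, edgeR adjusted p up to 0.0632), Tcf4 (any Control or Suv39DKO 2, up to 0.105) and Irf4 (any but Suv39DKO 1, up to 0.146). Without Suv39DKO replicate 1 there were 5 lower dendritic cell genes.

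Of the 4 tested members of the Y-linked list 1 was lower, Ddx3y, and 0 higher (list alone 2 and 0, too short a list for camera). Without Suv39DKO replicate 3, 2 members were lower. Ddx3y had 3012 to 3851 counts in controls and 2, 20 and 6 counts in Suv39DKO replicates 1, 2 and 3. Kdm5d, also on the Y chromosome, had 48.0 to 55.2 CPM in Suv39DKO against 56.9 to 66.3 CPM in Control and did not pass (-0.26, SE 0.09, edgeR adjusted p = 0.0729). Uty, with 710 to 1549 counts in the other libraries, had 7 counts in Suv39DKO replicate 3, and Eif2s3y had 16.6 CPM in Suv39DKO replicate 1 against 49.6 to 77.9 CPM in the other libraries. Values of Kdm5d, Uty and Eif2s3y were chosen after they were seen.

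Across the 36 tested lists, camera called 10, of which 4 were higher and 6 lower. The lower ones include the H3K9 list, which holds both targeted genes. With an estimated inter-gene correlation 0 were called, and fry called 6, those for positive selection, gamma delta and NK cells, neuronal genes, olfactory receptors, clustered multicopy families and histones. Median, mean and camera direction differed in sign for double positive identity, early thymocytes, effector T cells, B cells, interferon-stimulated genes, p53 targets, apoptosis, the unfolded protein response, MHC class I, predicted genes and serine protease inhibitors, none of them called.

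Distances between mice were larger in Suv39DKO than in Control. The mean distance between libraries was 46.4 within Control and 67.0 within Suv39DKO in log2 CPM units, a ratio of 1.44 (exact permutation p = 0.1, the smallest possible). The relabelled groups of that test mix the genotypes and hold the distances between them. Its p therefore cannot decide whether the spread within a genotype differed. The first principal component separated the genotypes and held 57.5% of the variance. The next held 17.2% and set Suv39DKO replicate 1 at -40.2 against 13.7 and 29.4 for replicates 2 and 3, with controls between -3.11 and 2.09. Genes lost at least 8-fold in 1 library alone, among genes at 2 CPM or more in the others, numbered 0 in each Control library and in Suv39DKO replicate 1, 4 in replicate 2, including Erbb3, and 4 in replicate 3, including Slc15a2 and Uty. Control replicate 2 had 1 such gain, Prtg. Genes were named here after their values were seen.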

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

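The count of neighbouring pairs without chromosome 12 was the 1 test here chosen only after the result was seen. Of the results that answer a comparison, most stayed within 1.5 times their value or on their side of the threshold, and the exceptions follow. Their cause was not tested except where fewer libraries or a stricter test explain it. A minimum fold of 1.5 in the test left 510 changed genes, 110 higher and 400 lower. With each library left out in turn, changed genes ranged from 1209 to 2224, higher genes from 446 to 1008 and lower genes from 763 to 1216, lowest in each case without Control replicate 2. Fits without a Control replicate shared 1251, 1173 and 1251 of their calls with the 2215. Lists called were 0 with an estimated inter-gene correlation, 6 by fry and 7 to 11 with a library left out. Genes gained from silence ranged from 82 to 101 with a library left out, against 64, since fewer libraries have to pass. The odds ratio near the targeted loci was 0.36 with 5 Mb, past 0.05 on the side of fewer changes, and that for higher genes near centromeres was 0.73 with the first 10 Mb and 0.94 with 30 Mb, no longer past it.

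Upper-quartile scaling called 2160 genes, 35.2% of them higher against 45.0% with the trimmed mean of M values, and moved the median of all genes to -0.03. DESeq2 called 2340 genes and limma-voom 2132. Without a filter 2988 were called. Pairs of neighbouring genes stayed above chance without pairs of the same family (124 higher, 168 lower) and without chromosome 12 (106 and 193; permutation p = 1e-04 for each). For the 142 named genes, 2361 of 2544 comparisons with an alternative kept direction and side of the threshold, 183 lost the threshold and 0 reversed. For lists, 336 comparisons kept their call status, 22 lost a call and 2 gained one.

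Replicate numbers do not pair the mice. Deviations from the group means correlated at -0.08, 0.03 and 0.07 for replicates 1, 2 and 3 across genotypes, and replicates 1 and 3 correlated better with another number. With the replicate number as a block 1907 genes were called, 815 higher and 1092 lower, and 10 lists. Depth limits calls of detection at 0.5 CPM, for which simulated libraries without planted switches still gave 16 gains and 25 losses.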

Other observations

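The tests of flanking sequence, of fewer blood cells of another type and of dilution by cells without receptor rearrangement were chosen only after the result was seen. The V segments of the T cell receptor alpha locus also differed by position. Of 70 tested, 3 were higher, Trav17 (log2 fold change 0.78), Trav16 (0.63) and Trav21-dv12 (0.56), and 2 lower, Trav7d-4 (-1.37) and Trav8n-2 (-1.20), all chosen after their values were seen. The median was 0.09 in the part near the J segments and -0.49 in the far part. In the Hoxa cluster Hoxa3 fell from 1.00 to 0.0267 CPM, Hoxa4 by 2.00 on the log2 scale and Hoxa6 from 1.16 to 0.0149 CPM, while Hoxb4 on chromosome 11 had 0.451 and 0.518 CPM and did not pass.

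With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. Every split other than the real one also mixes the genotypes, so the genotype difference lies inside its groups. Such splits are not a null for these counts, and no conclusion is drawn from them. The real split, the 1 of 10 with as many, called 2215 changed genes and the highest other 0. For genes lost from detection it gave 198, again the 1 of 10, and the highest other 22. For lists it gave 10 and the highest other 10, so 2 of the 10 splits called as many. The other splits called from 4 to 10 lists each while calling 0 changed genes.

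Of the 155 genes lost from detection and changed in the fit without the low-count filter, 0.645% lay within 20 Mb of a targeted gene. The share among the 13885 genes detected in controls was 1.09%, which argues against sequence carried along with the targeted alleles. Another lost gene lay within 2 Mb for 31.6% against a median of 32.9% and a 95th percentile of 40.6% in random placements. This argues against a few shared segments from another strain as the cause of the losses as a whole. Many scattered segments would not raise this share and stay open. Shared segments also stay open for single runs, since adjacent pairs of lower genes numbered 196 against 95.7 by chance. Lost genes lay close together at Hoxa3 to Hoxa7 and, on chromosome 3, at Gm6209, 5830415G21Rik, Gm37199 and Gm37461, chosen after their values were seen. Some of these overlap, since Hoxa3 spans Hoxa5 and Hoxa6, and Gm6209 spans 5830415G21Rik. Fewer cells of another type were set against a bound of -1 for the list medians. The lowest median was -0.41 (myeloid), and the lowest bootstrap bound among the 5 blood cell lists was -0.88 (B cells). This argues against a fall of 1 log2 unit or more in the medians of these lists, not against a smaller fall. The erythroid median was -0.16, with an interval from -0.35 to -0.03. Some members, such as Ly6d, are also expressed by thymocytes, so fewer blood cells of these types cannot be excluded. Fewer epithelial or stromal cells, which the CD45.2 gate would remove, cannot be told apart by this test, since the interval of their median (-0.28) ran from -1.06 to 0.12, and an effect of the missing enzymes stays open as a hypothesis.

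The cluster of 31 genes that rose on chromosome 12 could in principle reflect reads shared between near-identical copies. The median share of a member's 75-base words found in another annotated gene was 0.14, the highest 0.582. This argues against reads shared with other annotated transcripts as the whole cause. Copies outside the annotation and inexact matches were not searched. A variant form of this region carried by all Suv39DKO mice was not tested, since gene counts hold no sequence variants. Release of silencing over the span is an untested hypothesis beside it, which would need the H3K9 methylation and the sequence of the region in both groups.

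The rise of the 4 outermost J segments, with a median of -0.37 over the whole V-proximal part and -1.15 over the far part, may reflect less extensive rearrangement of the T cell receptor alpha locus in Suv39DKO cells, a hypothesis that predicts the V segments nearest the J segments to gain as well. Across the 70 V segments, which are not independent replicates, distance from the J segments and log2 fold change had a Spearman rho of -0.65 (permutation p = 1e-05, the smallest that 100000 permutations can give). The 31-base words of 38 J segments were found in another gene in a median share of 0. This argues against reads shared between J segments. V segments were not searched in this way, so an effect of reads shared between them on the V segment trend stays open. Dilution by cells without rearrangement cannot be told apart: the double positive identity list, with a median of 0.10, had members in both directions and such cells in this sort could express it, and Trdc, which rearrangement deletes, rose by 1.24. Whether the cells were at an earlier stage, shorter-lived or slower to rearrange was not tested.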
